A study of Rattus norvegicus with 40 samples.

How the data were processed

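Liver RNA of 40 rats, in 4 groups of 10, was measured on 1 array each, and the groups and doses were taken from the sample labels. The deposited values are log2 expression values per probe set in a table of all arrays, made by the authors with GCRMA and Partek, per the submitters' processing notes, whose versions are not given in the sources used here. GCRMA corrects each probe for background that depends on its sequence, normalizes between arrays and gives 1 log2 value per probe set, so that dim probe sets sit close to a floor and folds from that floor depend on the correction. The values were used as deposited, without a pseudocount or further background correction. Array data have no read depth, and the number of arrays limits the precision.

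Of 31139 probe sets, 19068 had 1 gene symbol in the platform annotation, 573 had several and 11498 were unnamed here. Symbols were updated through Entrez gene numbers, of which 18989 were matched in a RefSeq table of the GRCr8 assembly, used for names only. Probe sets with several genes named none. Per gene, the probe set with the highest mean over all 40 arrays was taken, which left 13438 genes, 3986 of them with more than 1 probe set. Control probe sets were left out of the gene tests.

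Each comparison was a contrast in 1 linear model with the 4 groups, fitted to all arrays with limma 3.58.1 (lmFit and eBayes, 36 residual degrees of freedom) in R 4.3.3. The tests were two-sided, and genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes of the comparison. The comparisons were each dose against vehicle and the steps from 0.1 to 1 and from 1 to 10 mg/kg. The dose course used the F test of the 3 dose contrasts. Gene lists were tested with camera at a preset correlation of 0.01, with adjustment over 56 lists of at least 3 measured genes, and again with an estimated correlation and with fry. The lists name 980 genes, of which 818 were found. Standard errors of list means are over arrays. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9.

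The groups, the tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. By that rule the text names, among genes past the threshold with the higher group mean at log2 5 or more, the 12 largest rises and 12 largest falls at 10 mg/kg, 10 and 10 at 1 mg/kg, 10 and 10 at 0.1 mg/kg and 5 and 5 for each step between doses. It also names up to 4 members of each described list with the largest changes at 10 mg/kg, and 20 genes whatever their values, of which 17 were measured. Symbols starting with LOC or RGD were passed over. Which lists to describe, and which of the genes the rule allows to show for them, were chosen after their values were seen.

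Quantile normalization of the deposited values was among the alternatives fixed in advance. Printing its counts beside every count at 1 and 10 mg/kg, and requiring both scales for a rise or fall, was decided after a shift of the scale between groups was seen. The others fixed in advance were other priors for the spread, fits of only the 2 groups compared, a filter keeping 5810 genes with a group mean at log2 5 or more, other ways to choose among probe sets, shifting arrays to 1 median, array weights, the replicate number as a block and a test against 1.2-fold. Added after seeing the data were scaling to 18 hybridisation control probe sets, quantile normalization with the filter or with the level of 24 poly-A control probe sets as a covariate, leaving out 2 arrays with a low upper quartile, leaving out each array in turn, and keeping only arrays 1 to 4 of the 1 mg/kg group, on the deposited scale or after quantile normalization.

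The tests were checked on data simulated for 13438 genes from the real means and spreads. In the comparison of 10 mg/kg with vehicle, 10 arrays against 10, they found 22% of genes changed 1.2-fold and 94% of those changed 1.5-fold. They found 98% of those changed 3-fold, and 11 of 166 calls were false. The adjustment depends on the number of calls, so these shares do not carry over to comparisons with fewer or more calls. The list test found the shifted list and called 0 of 20 unchanged lists. The simulated genes varied independently of each other, so this does not show how the list test treats correlated genes. The labels name separate rats within each group.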

Results

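Liver gene expression was measured in adult male Sprague Dawley rats treated with GW7647, a synthetic agonist of PPAR-alpha. PPAR-alpha is the nuclear receptor that binds fatty acids and controls genes of fatty acid breakdown in liver. There were 4 groups of 10 rats, which were given the solvent alone (vehicle) or a daily GW7647 dose of 0.1, 1 or 10 mg/kg by gavage over 4 days, and livers were taken 24 h after the last dose. Total RNA of each liver was hybridised to 1 Affymetrix array, which gave 40 arrays with 31139 probe sets each. The comparisons asked which transcripts differed from vehicle at each dose, and how the response grew from dose to dose. For each named gene 1 probe set was used, and 13438 genes were tested in every comparison.

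The scale of the deposited log2 values differed between the dose groups. The median of all probe sets was 2.47 ± 0.02 on the vehicle arrays, 2.47 ± 0.03 at 0.1 mg/kg, 2.60 ± 0.02 at 1 mg/kg and 2.71 ± 0.01 at 10 mg/kg (mean ± SD, n = 10 each). Against vehicle, the median log2 change of all genes was -0.03, 0.16 and 0.26 at the 3 doses, and 78.5% of genes lay above 0 at 1 mg/kg and 79.8% at 10 mg/kg. Bacterial transcripts added at the hybridisation step, read by 18 control probe sets, were 0.04, 0.17 and 0.23 higher than on the vehicle arrays. Vehicle and 0.1 mg/kg arrays shared 0.0263% exactly equal values on average over array pairs, close to the average of 0.0283% within the vehicle group, whereas the averages of the other pairs of different groups were at most 0.00164%. By these averages the 1 and 10 mg/kg groups each stood apart, although single pairs of arrays overlapped, from 0% to 0.0867% between vehicle and 0.1 mg/kg and up to 0.0128% between 1 and 10 mg/kg. Results at 1 and 10 mg/kg are therefore given on the deposited scale and after quantile normalization of all 40 arrays. If these groups were normalized in separate runs, run and dose cannot be told apart. Quantile normalization of finished values evens out whole arrays but need not remove an offset of a single probe set. Standard errors over arrays do not cover such offsets, so small changes at 1 and 10 mg/kg are less certain than their p-values. At 1 and 10 mg/kg a gene is said to have risen or fallen only where it passed the test in the same direction on both scales. This rule was chosen after the shift was seen. Because the deposited scale was shifted upward, quantile normalization mostly limits the rises under this rule, and the deposited scale mostly limits the falls. Counts under the rule, also within gene lists, therefore lean to rises. Folds are on the deposited scale unless stated otherwise. For gene lists at these doses the count adjusted over the list alone is the same as that over all genes unless another is given.

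Controls of sample preparation also differed with dose. RNAs with poly-A tails added before labelling, read by 24 probe sets, averaged 5.57 ± 0.37 in the vehicle group, 5.84 ± 0.28 at 0.1 mg/kg, 6.22 ± 0.73 at 1 mg/kg and 6.56 ± 0.38 at 10 mg/kg (log2, mean ± SD, n = 10 each). The 3′ minus 5′ signal of beta-actin, a sign of RNA and labelling quality, was 2.78 ± 0.24, 2.85 ± 0.36, 3.11 ± 0.61 and 3.22 ± 0.41 in the same order. Within the 1 mg/kg group the poly-A controls read 5.25 to 5.70 on arrays 1 to 4 and 6.34 to 7.39 on arrays 5 to 10. Relative to the array's gene median this step was 1.22 (SE 0.20), and 8 of 1000 random orders of the 10 arrays held a step as large (p = 0.00899). Arrays 1 to 4 did not lie above the vehicle arrays by this measure (-0.35, SE 0.17).

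**Figure D1:**
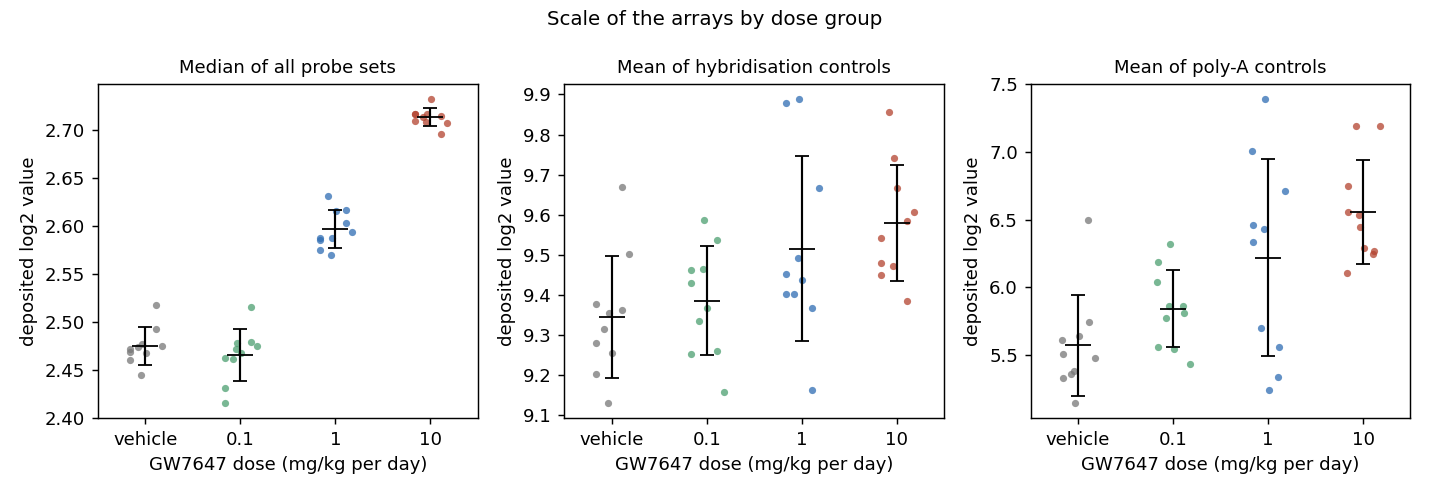
Each point is 1 array, with the mean and SD of the 10 arrays per dose group as bars, and the vertical axes give deposited log2 values for the median of all probe sets, the mean of the hybridisation controls and the mean of the poly-A controls against GW7647 dose in mg/kg per day. The median of all probe sets rose from 2.47 with vehicle to 2.71 at 10 mg/kg, and the poly-A controls rose from 5.57 to 6.56.

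At 0.1 mg/kg, enzymes of fatty acid oxidation rose in the liver. Aig1, a hydrolase of fatty acid esters of hydroxy fatty acids, rose 2.81-fold, from 4.40 ± 0.35 with vehicle to 5.89 ± 0.54 (log2, mean ± SD, n = 10 each, adjusted p = 3.59e-08), although another Aig1 probe set gave a log2 change of -0.07. Cyp4a1, which adds a hydroxyl group to the end of fatty acids, rose 1.86-fold with a standard error of 0.10 on the log2 scale. Pex11a, which acts in peroxisome division, rose 1.80-fold, and Acot2, a mitochondrial acyl-CoA thioesterase, rose 1.65-fold. Eci1 and Ech1, isomerases needed to oxidise unsaturated fatty acids, rose 1.73-fold and 1.64-fold.

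Smaller rises at 0.1 mg/kg were those of Ehhadh, the peroxisomal bifunctional enzyme (1.42-fold), Decr1, a reductase of unsaturated fatty acid oxidation (1.34-fold), Vwa8, a mitochondrial protein (1.33-fold), and Acaa2, the mitochondrial thiolase (1.22-fold). Hadhb, the beta subunit of the mitochondrial trifunctional protein, also rose 1.22-fold, with adjusted p = 0.0114. Spin2b fell by 1.24 on the log2 scale (adjusted p = 0.0041) and was also lower at 1 and 10 mg/kg, by log2 changes of -1.49 and -1.85, which end at dim levels of 2.54 and 2.19. Ermard had a log2 change of -0.46 with adjusted p = 0.0343, which became 0.102 after quantile normalization, and it was 0.57 higher at 10 mg/kg. Hadhb, Spin2b and Ermard lie outside the rule for named genes and were chosen after their values were seen. Several genes of the same metabolism did not pass at this dose. Cpt1a, the liver-type enzyme that starts fatty acid entry into mitochondria, had a log2 change of 0.15 (SE 0.15), the thioesterase Acot1 had 0.17, and Vnn1, a pantetheinase, had 0.64 with adjusted p = 0.763.

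Of 56 gene lists fixed in advance, 3 stood higher than other genes at 0.1 mg/kg with either treatment of the correlation between genes. Among 20 genes of mitochondrial beta-oxidation and the carnitine shuttle 4 rose and 0 fell, or 7 when adjusted over the list alone, with adjusted p = 1.26e-18 and adjusted p = 0.000207 with an estimated correlation. Of 18 genes of peroxisomal beta-oxidation 2 rose (4 when adjusted over the list alone; adjusted p = 3.62e-08, and adjusted p = 0.0256 with an estimated correlation). A reference list of 39 PPAR-alpha target genes, which shares members with both, had 8 that rose, or 11 adjusted over the list alone, with adjusted p = 2.12e-19 and adjusted p = 0.000933 with an estimated correlation. Interferon-stimulated genes had a median log2 change of 0.11 with 0 of 19 past the threshold, and their call was lost at adjusted p = 0.475 with an estimated correlation. Cell cycle genes had a median of -0.13 with 0 of 35 past the threshold, and their call was lost at adjusted p = 0.7 with an estimated correlation.

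In all, 13 of 13438 genes differed at 0.1 mg/kg in limma's moderated test at an adjusted p under 0.05, 11 higher and 2 lower, and 6 of those higher reached 1.5-fold. After quantile normalization the count was also 13, with 12 higher and 1 lower. At an unadjusted p under 0.05 there were 587. The count was 7 when only these 2 groups were fitted, 7 after scaling to the hybridisation controls, and 4 when a change beyond 1.2-fold was required. In simulated data of the same size the test found 14% of genes changed 1.2-fold and 92% of those changed 1.5-fold. Of its 163 calls in these data 10 were false. The adjustment over all genes is stricter with 13 calls than with 163, so these shares are likely too high for the real comparison.

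At 1 mg/kg more genes of fatty acid metabolism rose. Acot1 rose from 1.65 ± 0.19, below the vehicle arrays' lower quartile of 1.91, to 10.71 ± 0.25 (log2, mean ± SD, n = 10 each), so that the size of its fold depends on the background correction of a dim probe set. Aig1 rose 22.4-fold, Acot2 11.7-fold and Crat, carnitine acetyltransferase, 10.7-fold. Vnn1 rose 9.90-fold, Cyp4a1 7.65-fold, Aldh1a1, which makes retinoic acid, 6.66-fold and Ehhadh 6.33-fold. Outside fatty acid metabolism, Hdc, the enzyme that forms histamine, rose 26.3-fold from 4.15 ± 0.37 to 8.87 ± 0.34, Spmip11 rose 12.5-fold from a dim 2.15 ± 0.14, and Spink1, a protease inhibitor, rose 7.85-fold.

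Among genes bright enough to be named, those with the largest falls at 1 mg/kg were mixed in function. Apoa4, an apolipoprotein of triglyceride-rich particles, fell by 2.68 on the log2 scale, from 10.66 ± 0.27 to 7.98 ± 0.60 (n = 10 each, adjusted p = 4.92e-13). Elapor1 changed by -1.67, Mtmr7, a lipid phosphatase, by -1.45, the P450 gene Cyp3a9 by -1.14 and RT1-CE16, a class I antigen-presenting molecule, by -1.10. Dio1, which activates thyroid hormone, changed by -1.01, the immediate-early gene Egr1 by -0.92 (adjusted p = 0.0472) and Extl1 by -0.89. Aldh1b1 changed by -0.87 and Bhlhe40, a repressor of the circadian clock, by -0.85. Egr1 did not pass at 0.1 mg/kg (-1.54, adjusted p = 0.185) or at 10 mg/kg (-0.43, adjusted p = 0.323).

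Among the genes named whatever their values, Pdk4, which restrains pyruvate oxidation, rose 2.50-fold at 1 mg/kg, Angptl4, an inhibitor of lipoprotein lipase, 2.7-fold, Cpt1a 2.12-fold, Cpt1b 5.67-fold from a dim level and Cyp8b1, the sterol 12-hydroxylase of bile acid synthesis, 2.18-fold. Plin2, a coat protein of lipid droplets, rose by 0.45 on the log2 scale, while another of its probe sets gave -0.13. Mki67, a marker of dividing cells, passed the test, but at 1.85 and 2.36 it lay below the array medians in both groups, and so did Ppara. Fgf21, a fasting hormone, had 0.53 (adjusted p = 0.139), Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had 0.68 (adjusted p = 0.0668) and Ppara itself did not pass (adjusted p = 0.23). Ccnd1, a cyclin of the G1 phase, had 0.54 on the deposited scale with adjusted p = 0.0181 but 0.28 with adjusted p = 0.288 after quantile normalization.

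All 20 measured genes of mitochondrial beta-oxidation and the carnitine shuttle rose at 1 mg/kg, with a median log2 change of 0.91 on the deposited scale and 0.72 after quantile normalization (adjusted p = 5.97e-06 with an estimated correlation). The same count was found when adjusted over the list alone. Of 18 peroxisomal beta-oxidation genes 12 rose and 0 fell (13 when adjusted over the list alone), of 7 acyl-CoA thioesterases 6 rose, and of 39 PPAR-alpha reference genes 33 rose (34 adjusted over the list alone). For fatty acid uptake, binding and activation 12 of 22 rose and 0 fell, with the same 12 when adjusted over the list alone and adjusted p = 0.0349 with an estimated correlation. Cell cycle and DNA replication genes moved too, with 24 of 35 that rose and 0 that fell, among them the mitotic cyclins Ccnb1 and Ccnb2, both by 2.25, and the mitotic activator Cdc20 by 2.16. That list's call was lost at adjusted p = 0.249 with an estimated correlation.

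Genes of energy production rose in part at 1 mg/kg. In the tricarboxylic acid cycle 7 of 13 rose and 0 fell (adjusted p = 0.0349 with an estimated correlation), and in the respiratory chain and ATP synthase 14 of 36 rose and 0 fell (adjusted p = 0.0349 with an estimated correlation, 0.079 after quantile normalization). Adjusted over the list alone these counts were 8 and 16. Of 28 proteasome genes 12 rose (13 adjusted over the list alone), with adjusted p = 0.128 with an estimated correlation. Among secreted liver proteins, 5 of 18 complement genes fell (4 adjusted over the list alone, adjusted p = 0.0259 with an estimated correlation). Apart from these, 4 of 12 genes of the periportal zone fell (5 adjusted over the list alone, adjusted p = 0.0349 with an estimated correlation). Acute-phase genes stood lower than other genes with adjusted p = 0.0349 with an estimated correlation although their median log2 change was 0.02, with 3 of 18 that fell and 2 when adjusted over the list alone. Of 11 macrophage markers 4 fell, and their call was lost at adjusted p = 0.132 with an estimated correlation. The poly-A controls were 0.65 higher in the same comparison.

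On the deposited scale 5594 genes differed at 1 mg/kg, 5141 higher and 453 lower, so that 91.9% were higher. After quantile normalization 3106 differed, 1485 higher and 1621 lower, or 47.8% higher. On both scales 1485 rose and 453 fell. The 1485 are all the genes higher after quantile normalization, and the 453 are all the genes lower on the deposited scale. A change of at least 1.5-fold was found for 887 higher and 66 lower genes on the deposited scale and for 290 and 217 after quantile normalization. Scaling to the hybridisation controls left 1737 genes, and 70 of the 1733 called genes with several probe sets had another one past the threshold in the opposite direction.

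At 10 mg/kg genes for fatty acid binding and entry into mitochondria were among those with the largest rises. Fabp3, the fatty acid binding protein typical of heart, rose 116-fold, from 3.69 ± 0.34 to 10.55 ± 0.62, and Cpt1b, the carnitine palmitoyltransferase typical of muscle, rose 76.0-fold, from 2.29 ± 0.10 to 8.54 ± 0.34 (log2, mean ± SD, n = 10 each). The vehicle level of Cpt1b lay below the vehicle arrays' median of 2.47, so that the size of its fold depends on the background correction too. Acot1 reached 11.56 ± 0.10. Vnn1 rose 28.8-fold, Crat 23.3-fold and Acot2 17.1-fold. Cyp4a1 rose 9.59-fold and Ehhadh 8.77-fold. Pdk4 rose 6.27-fold, Angptl4 3.83-fold, Cpt1a 3.20-fold and Fgf21 2.65-fold.

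All 20 mitochondrial beta-oxidation genes rose at 10 mg/kg, also when adjusted over the list alone, with a median log2 change of 1.24 (0.98 after quantile normalization) and adjusted p = 7.22e-05 with an estimated correlation. Examples were Eci1 (6.34-fold), Hadha, the alpha subunit of the trifunctional protein (4.81-fold), and Slc22a5, a carnitine transporter (4.28-fold). In peroxisomal beta-oxidation 13 of 18 rose and 2 fell (14 and 2 adjusted over the list alone), with Ech1 up 8.01-fold and the thioesterase Acot8 up 4.77-fold. The list's adjusted p was 0.0207 with an estimated correlation. Of 16 genes of peroxisome biogenesis 5 rose and 11 did not pass on both scales. They included Pex11a (12.7-fold), Pex19, a carrier of membrane proteins (5.10-fold), and Pex6, an ATPase of protein import (2.13-fold), and the list's call was lost at adjusted p = 0.309 with an estimated correlation. Of 7 acyl-CoA thioesterases 6 rose, among them Acot7 by 5.14-fold. Whether the probe sets of near-identical thioesterases read each other's transcripts was not examined. Of 39 PPAR-alpha reference genes 36 rose and 1 fell, with the same counts when adjusted over the list alone (adjusted p = 7.18e-05 with an estimated correlation). The Cyp4 list was split, with 3 that rose, 3 that fell and 4 that did not pass. Cyp4a3 rose 2.97-fold, while Cyp4a8 had a log2 change of -0.81, down to a dim 2.24, and another of its probe sets gave 0.03.

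Genes of fatty acid uptake, storage and synthesis rose together with those of oxidation at 10 mg/kg. For uptake, binding and activation 14 of 22 rose and 0 fell, also when adjusted over the list alone (adjusted p = 0.0122 with an estimated correlation), with Lpl, lipoprotein lipase, up 14.5-fold, the fatty acid transporter Cd36 up 6.86-fold and the acyl-CoA synthetase Acsl3 up 6.14-fold. For lipid droplets and triglyceride turnover 12 of 20 rose and 2 fell, also when adjusted over the list alone (adjusted p = 0.0442 with an estimated correlation). Cidea, which enlarges droplets, rose 15.6-fold, the droplet protein Plin5 8.02-fold, the lipase Pnpla3 7.98-fold and Mgll, monoglyceride lipase, 5.26-fold, whereas Plin2 rose 2.20-fold with one probe set and had a log2 change of -0.08 with another. For lipogenesis and desaturation 14 of 19 rose and 0 fell, also when adjusted over the list alone (adjusted p = 0.0369 with an estimated correlation). Malic enzyme Me1 rose 8.53-fold, the elongase Elovl6 8.38-fold and the desaturases Scd2 and Fads2 8.25-fold and 4.59-fold. Other genes high in this comparison were Adig, a small protein of fat cells (55.7-fold), the glycerol channels Aqp7 (33.0-fold) and Aqp3 (32.3-fold), and Cacna2d3, a calcium channel subunit (38.1-fold). Spmip11, Aig1 and Hdc rose 55.4-fold, 44.4-fold and 42.6-fold. White fat cell markers did not stand apart (adjusted p = 0.879). The mean change of 6 such markers was 0.32 (SE 0.07) on the deposited scale and 0.05 (SE 0.07) after quantile normalization, and 2 of the 6 rose, the hormone-sensitive lipase gene Lipe (1.07 and 0.82 on the log2 scale) and Adipoq (0.49 and 0.23), which was dim. Another Lipe probe set did not pass. Cacna2d3, Aqp3, Aqp7, Adig and Spmip11 were dim with vehicle, at 1.81, 1.85, 1.96, 2.05 and 2.15, below the arrays' median, and the sizes of these 5 folds depend on the background correction as well.

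**Figure D2:**
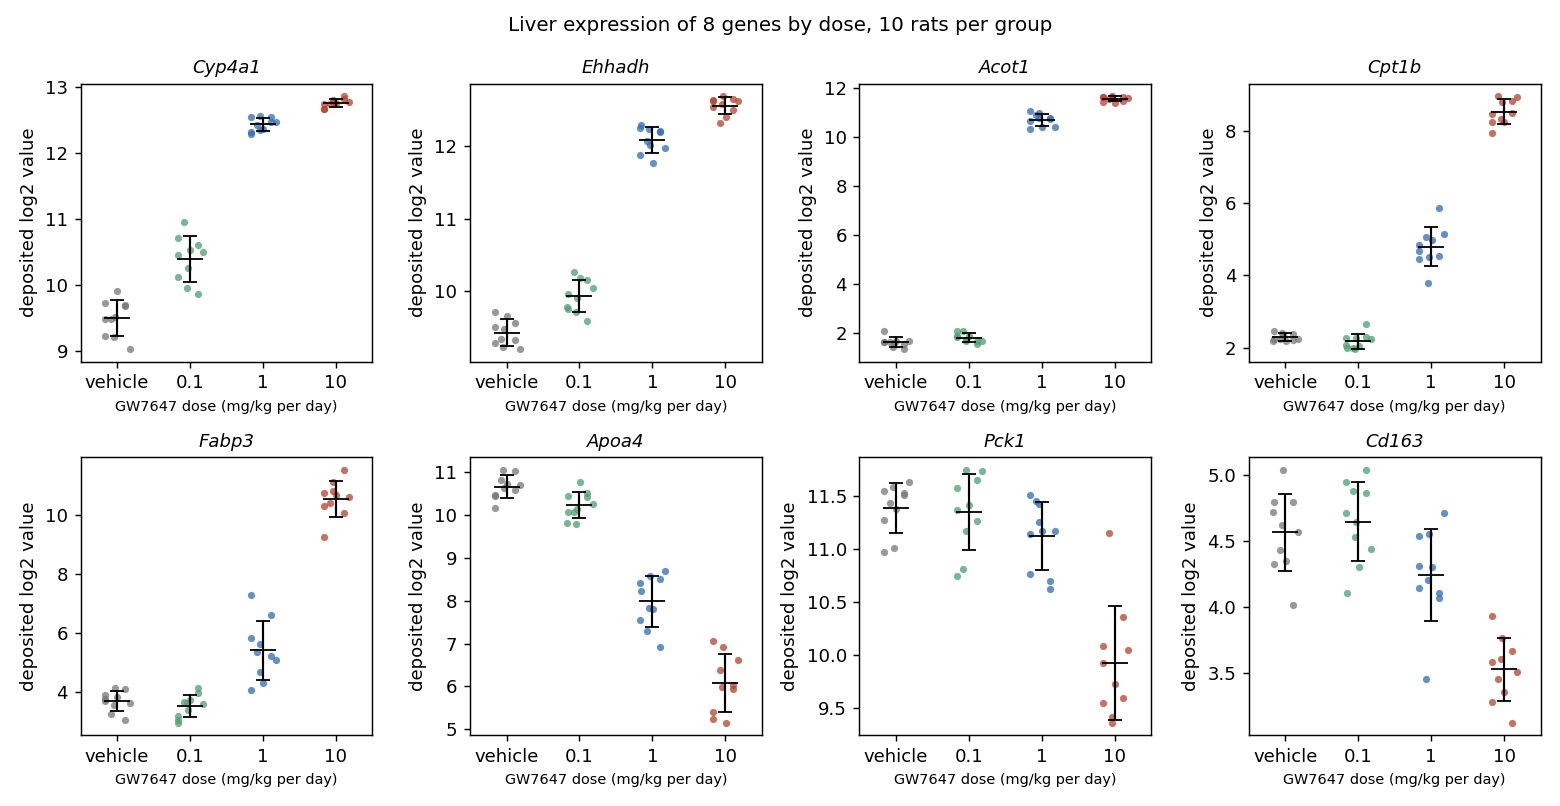
Each point is 1 rat liver, with the mean and SD of the 10 rats per group as bars, and the vertical axes give the deposited log2 value of 8 genes against GW7647 dose in mg/kg per day. Cyp4a1 rose from 9.50 with vehicle to 12.44 at 1 mg/kg and 12.76 at 10 mg/kg, Fabp3 rose from 5.41 at 1 mg/kg to 10.55 at 10 mg/kg, and Apoa4 fell from 10.66 with vehicle to 6.07 at 10 mg/kg.

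Lists of mitochondrial energy production and protein turnover rose by smaller amounts at 10 mg/kg. In the respiratory chain and ATP synthase 25 of 36 rose and 0 fell, also when adjusted over the list alone, with a median log2 change of 0.54 on the deposited scale and 0.27 after quantile normalization (adjusted p = 0.0142 with an estimated correlation). The complex I subunits Ndufb10 and Ndufs4 changed by 0.82 and 0.77, or 0.53 and 0.45 after quantile normalization. In the tricarboxylic acid cycle 8 of 13 rose (adjusted p = 0.0349 with an estimated correlation), with Suclg1 at 1.06 and Ogdh at 0.96. Of 28 proteasome genes 23 rose and 0 fell, also when adjusted over the list alone (adjusted p = 0.0334 with an estimated correlation), with Psmd2 at 1.06 and Psmb7 at 1.03. Of 26 cytosolic ribosomal protein genes 9 rose, with Rpl18 at 0.68 and at 0.39 after quantile normalization, and that call was lost at adjusted p = 0.115 with an estimated correlation. Of 5 uncoupling proteins 3 rose, Ucp2 by 2.30-fold, Ucp3 from 2.48, at the vehicle arrays' median, to 5.13, and Ucp1, which was dim in both groups. The size of the Ucp3 change depends on the background correction, and the list's call was lost at adjusted p = 0.0649 with an estimated correlation. Hspb1, a small heat shock protein, rose 7.66-fold and the mitochondrial chaperone Hspd1 1.94-fold, but the heat shock list did not pass (5 of 13 rose, adjusted p = 0.0799). The poly-A controls were 0.99 higher in the same comparison and the beta-actin 3′ minus 5′ signal was 3.22 ± 0.41 against 2.78 ± 0.24. Vehicle array 1, which had the highest poly-A controls of its group (6.50), was also its highest array in Psmd2 (8.85 against 8.13 to 8.48), Rpl18 (11.05 against 10.54 to 10.81) and Ogdh (8.01 against 7.37 to 7.65), the direction of the change at 10 mg/kg. Its beta-actin signal (2.20) and its Lpl value (2.52) were the lowest of the group, the opposite direction. These genes were picked because this array stood apart in them, so they do not show whether whole lists follow the poly-A controls. Without this array 8570 genes were called at 10 mg/kg, against 8627 with it.

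Apoa4 was the gene with the largest fall at 10 mg/kg among those bright enough to be named, 24-fold, from 10.66 ± 0.27 to 6.07 ± 0.68 (log2, mean ± SD, n = 10 each, adjusted p = 3.73e-21). Of 19 genes of apolipoproteins and lipoprotein remodelling 10 fell and 2 rose, also when adjusted over the list alone (adjusted p = 0.00204 with an estimated correlation). Apoa5, an activator of lipoprotein lipase, changed by -0.80, while Abca1, a cholesterol exporter, rose by 1.01 and Mttp, needed to assemble lipoproteins, by 0.72. Elapor1 changed by -3.13, Stac3 by -2.62, the glucuronosyltransferase Ugt2b1 by -2.36, Cyp3a9 by -2.36 and Mt2A, a metallothionein, by -2.11. Mtmr7 and Mmd2 both changed by -1.87 and the chemokine Cxcl1 by -1.84. Mlc1 changed by -1.76 with wide spreads, from 6.08 ± 1.89 to 4.32 ± 1.01 (adjusted p = 0.0317).

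Part of the genes for secreted plasma proteins and for enzymes of the periportal zone fell at 10 mg/kg. Of 18 complement genes 13 fell and 0 rose, also when adjusted over the list alone (adjusted p = 0.000149 with an estimated correlation), including C6 (-1.26), C1s (-0.95) and the lectins Mbl1 (-0.78) and Mbl2 (-0.71). In the coagulation list 7 of 18 fell and 0 rose on both scales (adjusted p = 0.0126 with an estimated correlation), with Cpb2, an inhibitor of clot lysis, at -0.66 and prekallikrein, Klkb1, at -0.47. Of 18 acute-phase genes 7 fell and 0 rose on both scales (adjusted p = 7.22e-05 with an estimated correlation), with A2m at -2.07, Saa4 at -0.80 and Apcs at -0.74. These 7 and 7 were also found when adjusted over the list alone, and the median log2 changes of these lists depended on the scale. They were -0.08 for coagulation and -0.09 for acute-phase genes on the deposited scale, and -0.38 and -0.34 after quantile normalization, on which 16 of 18 and 13 of 18 genes were lower. Of 12 periportal genes 8 fell and 1 rose, also when adjusted over the list alone (adjusted p = 0.000585 with an estimated correlation). Among them Sds, which degrades serine, changed by -2.12, Pck1, the first committed enzyme of gluconeogenesis, by -1.47, the urea cycle enzyme Ass1 by -1.44 and Hal, which degrades histidine, by -1.31. The list of urea cycle and amino acid breakdown had 12 of 36 that fell and 3 that rose, with Acmsd at -1.79, down to a dim 2.63, and its call was lost at adjusted p = 0.055 with an estimated correlation. The poly-A controls were 0.99 higher in the same comparison, and vehicle array 1, with the highest poly-A controls of its group, was its lowest array in Apcs (11.12), Cpb2 (10.91) and Mbl2 (9.71, against 9.65 ± 0.20 at 10 mg/kg). These genes too were picked because this array stood apart in them.

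Cell cycle and DNA replication genes rose at 10 mg/kg in 23 of 35 cases and fell in 0 (26 rose when adjusted over the list alone). Ccnb2 rose 6.38-fold, Ccnb1 5.34-fold, Cdc20 5.09-fold and the mitotic kinesin Kif20a 4.48-fold. The list had adjusted p = 5.18e-05, which was lost at adjusted p = 0.299 with an estimated correlation. Mki67 was dim, at 1.85 ± 0.17 with vehicle and 2.64 ± 0.45 at 10 mg/kg, below the array medians, so no fold is given although it passed the test. Ccnd1 had 0.44 with adjusted p = 0.0375 on the deposited scale and 0.12 with adjusted p = 0.636 after quantile normalization. The poly-A controls were 0.99 higher at this dose too. At 0.1 mg/kg, however, these controls were 0.27 higher. The log2 changes of Ccnb1, Ccnb2, Cdc20 and Kif20a were then -0.43, -0.44, -0.44 and -0.31, none of which passed.

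Genes of bile acid and foreign compound metabolism went both ways at 10 mg/kg. Cyp7a1 rose 3.02-fold, Cyp8b1 2.26-fold and Nr0b2, a nuclear receptor that represses bile acid synthesis, 3.63-fold. The list of bile acid synthesis and transport had 7 of 18 that rose and 1 that fell, and did not stand apart from other genes (adjusted p = 0.85). In the list of P450s and transporters under control of the receptors CAR and PXR 5 of 14 rose and 5 fell. Aldh1a1 rose 10.6-fold and the P450 electron donor Por 2.96-fold, against the falls of Ugt2b1 and Cyp3a9. This list ranked lower than other genes with adjusted p = 0.038 although its median log2 change was 0.08, and the call was lost at adjusted p = 0.0776 with an estimated correlation. Cyp1a1, a target of the aryl hydrocarbon receptor, was dim, at 2.16 with vehicle and 2.03 at 10 mg/kg, and so was Ppara, at 2.17 and 2.62. All 4 values lie below the array medians of 2.47 and 2.71, and neither gene passed on both scales, so no change is given for them.

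Of 11 macrophage markers 10 fell and 0 rose at 10 mg/kg, also when adjusted over the list alone. The scavenger receptor Cd163 changed by -1.03, the complement subunit C1qb by -0.96, the Kupffer cell lectin Clec4f by -0.86 and Cd5l by -0.90, although another Cd5l probe set gave 0.22. The list had adjusted p = 0.0369 with an estimated correlation, and 0.109 with one after quantile normalization. Its mean change was -0.70 with a standard error of 0.13, or -1.0 after quantile normalization, where 10 of 10 arrays lay below the lowest vehicle array. The same 10 of 10 held on that scale for the endothelial markers (mean change -0.34, SE 0.04) and for the T and natural killer cell markers (-0.34, SE 0.05), with 8 of 10 for B cell markers and 9 of 10 for hepatocyte markers. Of 10 endothelial markers 3 fell, including Flt4 (-0.47) and Tek (-0.44), in a list whose median was 0.00 and whose call was lost at adjusted p = 0.0776 with an estimated correlation. Of 15 T and natural killer cell markers 2 fell, including Lck (-1.24), and that call was lost at adjusted p = 0.128 with an estimated correlation. The mean change of 11 hepatocyte markers was 0.03 on the deposited scale and -0.12 after quantile normalization.

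**Figure D3:**
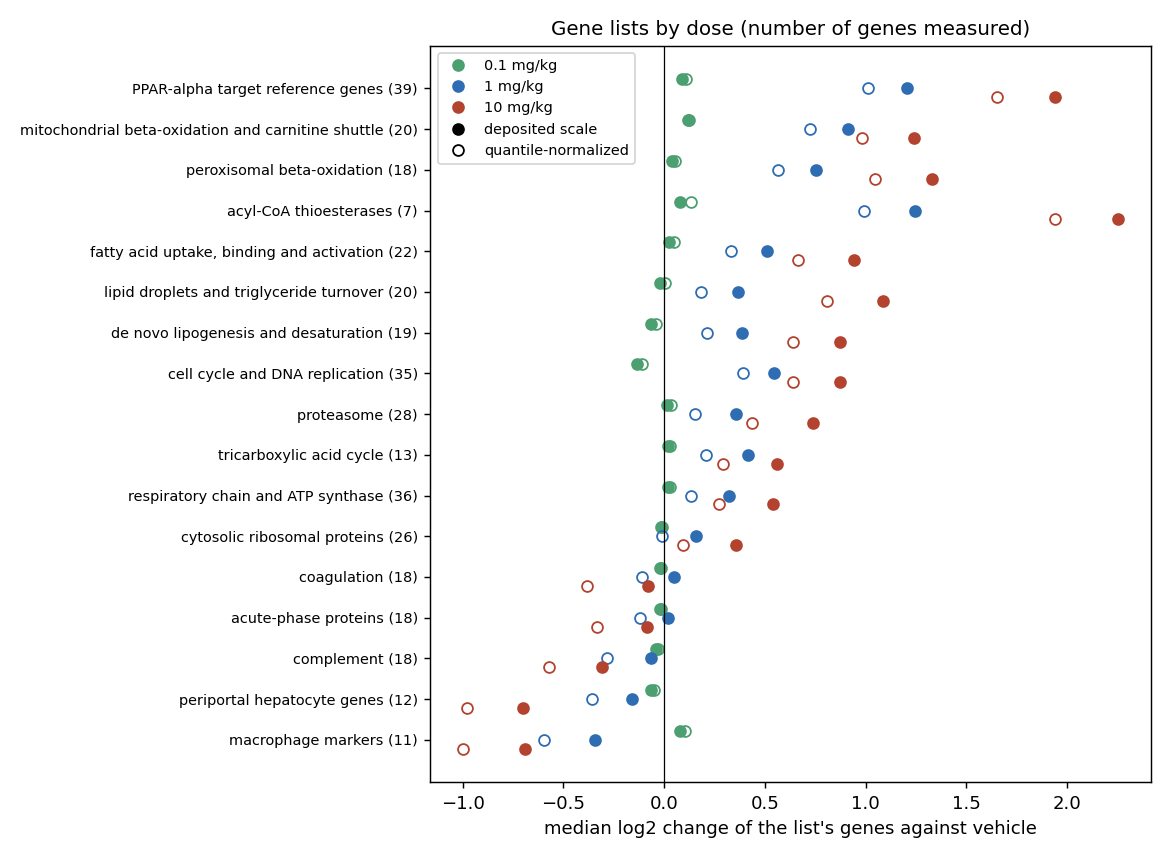
Each row is a gene list with its number of measured genes, and points give the median log2 change of its genes against vehicle on the horizontal axis for the 3 doses, filled on the deposited scale and open after quantile normalization. At 10 mg/kg the PPAR-alpha reference genes lie at 1.94 and 1.65 on these scales and the macrophage markers at -0.69 and -1.0, while the median of coagulation genes at 1 mg/kg changes sign between the scales.

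On the deposited scale 8627 of 13438 genes differed at 10 mg/kg in limma's moderated test, 7594 higher and 1033 lower, or 88.0% higher. After quantile normalization 6022 differed, 2749 higher and 3273 lower, or 45.6% higher. On both scales 2749 rose and 1033 fell, while 36 genes were called in opposite directions by the 2 scales. The 2749 are all the genes higher after quantile normalization, and the 1033 are all the genes lower on the deposited scale. The excess of rises among them thus comes in part from the rule. At least 1.5-fold changes were found for 1994 higher and 295 lower genes on the deposited scale and for 748 and 800 after quantile normalization. Of the gene lists 35 passed with a preset correlation and 16 with an estimated one. Scaling to the hybridisation controls left 4024 genes, and 216 of the 2411 called genes with several probe sets had another one past the threshold in the opposite direction.

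From 0.1 to 1 mg/kg Acot1 rose from a level at background, 1.82 ± 0.18, so that its log2 difference of 8.89 depends on the background correction. Next in size by the rule for named genes were Hdc (4.16 on the log2 scale), Spmip11 (3.21, from a dim 2.57), Aig1 (2.99) and Crat (2.90). Apoa4 changed by -2.25, Elapor1 by -1.50, RT1-CE16 by -1.33, A2m by -1.02 and Ms4a6a, a membrane protein of macrophages, by -0.98. In this step 6506 genes differed on the deposited scale, 6109 higher and 397 lower, and 2942 after quantile normalization, 1407 higher and 1535 lower. On both scales 1407 rose and 397 fell. The share of higher genes was 93.9% on the first scale and 47.8% on the second.

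From 1 to 10 mg/kg other genes led. Fabp3 rose by 5.14 on the log2 scale, Cpt1b by 3.75, Adig by 3.52, Lpl by 3.38 and Pnpla3 by 3.15. Lpl and Pnpla3 had not passed at 1 mg/kg against vehicle, where their log2 changes were 0.47 (adjusted p = 0.131) and -0.16 (adjusted p = 0.817). Sds changed by -2.52, Apoa4 by -1.91, Ugt2b1 by -1.88, Stac3 by -1.77 and Mt2A by -1.73. Cyp4a1, Ehhadh and Acot1 rose by 0.33, 0.47 and 0.85 in this step, to 12.76, 12.56 and 11.56, near the highest values of the arrays, about 13.5, so that compression of bright signals was not excluded. The cyclin Ccnb1 had 0.17 with adjusted p = 0.645. On the deposited scale 4110 genes differed, 3256 higher and 854 lower (79.2% higher), and after quantile normalization 2462, 1153 higher and 1309 lower (46.8% higher). On both scales 1149 rose and 804 fell.

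Most genes that differed at 0.1 mg/kg differed in the same direction at the higher doses, with 12 of 13 also called at 1 mg/kg and 12 of 13 at 10 mg/kg. Independent lists of these lengths would share 4.3 and 6.4. Ermard was called in opposite directions at 0.1 and 10 mg/kg. Between 1 and 10 mg/kg 4825 genes were shared in the same direction and 26 in opposite directions, where independent lists would share 2940.1. After quantile normalization the 3 overlaps were 13, 13 and 2556, against 1.4, 2.7 and 698.6 for independent lists. Simulated groups with no change, tested against the same vehicle arrays in 100 draws, shared 0 genes, which leaves the part of the shared vehicle arrays unmeasured since such groups gave at most 2 calls. The covariance of log2 changes over all genes holds that part together with any response or offset that 2 doses share. It was 0.00894 for 0.1 and 1 mg/kg, 0.0143 for 0.1 and 10 mg/kg and 0.119 for 1 and 10 mg/kg. The means in the simulated draws, whose genes varied independently, were 0.00703, 0.00703 and 0.00701. Most of the covariance of 0.1 and 1 mg/kg is thus of the size that shared vehicle arrays alone give. Each dose was also tested against either the odd- or the even-numbered vehicle arrays, so that no vehicle array was shared. The overlap of 1 and 10 mg/kg was then 3107 or 3394, against 1747.2 or 2016.4 for independent lists. Of the 13 or 9 genes called at 0.1 mg/kg in these tests, 10 or 9 were shared with 1 mg/kg, against 2.9 or 2.3. With 10 mg/kg 10 or 9 were shared too, against 4.8 or 4.3.

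Across the 4 groups 9540 genes differed at some dose on the deposited scale. The means of 2802 of them, or 29.4%, followed the order of the doses, 2431 rising and 371 falling. Of all possible orders of 4 groups 8.33% rise or fall throughout, which is not a no-change value for genes chosen by a test or for a scale whose group medians are themselves ordered. After quantile normalization 2544 of 6437 genes followed the order, or 39.5%, with 1168 rising and 1376 falling. Vnn1, from 5.66 with vehicle through 6.31 and 8.97 to 10.51, and Apoa4, from 10.66 through 10.23 and 7.98 to 6.07, are examples of either direction. Of 4202 genes of at least log2 5 in 1 group that differed, 1383 followed the order.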

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

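All tests of explanations below were chosen after the result was seen. In each group of 10 arrays the highest and the lowest value were set against the others, for array measures and for genes named in the text, by the gap to the next array as a share of the group's range. Of 548 such groups 39, or 7.1%, were past the limit, where chance alone marks about 1 in 20, or 27.4.

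Vehicle array 1 was set apart most often. The gap made up 0.51 of the range for its lower quartile (1.95 against 1.89 to 1.92 on the other vehicle arrays), 0.556 for its poly-A controls (6.50 against 5.15 to 5.75) and 0.505 for its beta-actin 3′ minus 5′ signal (2.20 against 2.68 to 3.14). It was highest in Acot7 (0.494), Ogdh (0.552), Psmd2 (0.516) and Rpl18 (0.473), and lowest in Apcs (0.478), Cpb2 (0.513), Lpl (0.611) and Mbl2 (0.516). In Acot7, Ogdh, Psmd2, Rpl18, Apcs, Cpb2 and Mbl2 this vehicle array deviated in the direction of the change at 10 mg/kg, while in Lpl and in the beta-actin signal it deviated in the opposite one. Without this array 15, 5549 and 8570 genes were called at 0.1, 1 and 10 mg/kg. On array 2 of the 10 mg/kg group the upper quartile was low (0.746, 4.89 against 5.07 to 5.13), and so was Mmd2 (0.536). The gap rule passes over 2 low arrays in 1 group: 0.1 mg/kg arrays 8 and 9 had upper quartiles of 4.27 and 4.47, against 4.76 to 4.87 on the other arrays of that group.

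Other vehicle arrays stood apart in single genes, with the gap's share of the range in brackets. Array 5 was highest in A2m (0.497) and Acot1 (0.537), array 9 in Asns (0.554), array 2 in Cyp4a8 (0.575) and array 7 in Mki67 (0.515), while array 6 was lowest in Aig1 (0.499), array 4 in Ech1 (0.507) and array 10 in Elapor1 (0.478). At 0.1 mg/kg, array 2 was highest in Cpt1b (0.512) and lowest in Cyp7a1 (0.544), array 10 was highest in Cyp4a8 (0.509) and array 4 in Scd2 (0.542). At 1 mg/kg, array 1 was highest in Aldh1a1 (0.531), array 4 lowest in Cd163 (0.488) and highest in Adipoq (0.545), array 9 lowest in Crat (0.513) and Plin2 (0.5) and array 10 lowest in Psmb7 (0.48). At 10 mg/kg, array 4 was lowest in Aldh1a1 (0.583) and Ermard (0.548) and highest in Cxcl1 (0.595) and Egr1 (0.777, at 8.35 against 4.37 to 5.26). Array 1 was lowest in Apoa5 (0.484) and highest in Asns (0.488), array 8 was lowest in Lss (0.493) and array 7 highest in Per3 (0.59).

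Outside the genes tested, the poly-A controls were 0.99 higher at 10 mg/kg than with vehicle. Of the 11498 unnamed probe sets 11407 were tested here. Among these, 2331 differed at 10 mg/kg on both scales, 1904 higher and 427 lower, and 0 differed at 0.1 mg/kg. Of 573 probe sets with several genes, 134 were higher and 40 lower at 10 mg/kg on both scales, and 2 were higher at 0.1 mg/kg.

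The median of all genes was higher at 1 and 10 mg/kg on the deposited scale. After scaling each array to its hybridisation controls the median change at 10 mg/kg was 0.023 with a standard error of 0.067. A rise of the genes as a whole relative to these controls was thus not shown. The standard error leaves room for a rise smaller than the 0.26 on the deposited scale. Since the controls are added only at the hybridisation step, this cannot decide whether most transcripts rose in the liver cells. Separate normalization runs for the 1 and 10 mg/kg arrays are a candidate explanation. Groups of different supposed runs shared at most 0.00164% exactly equal values on average over array pairs, against 0.0263% on average between vehicle and 0.1 mg/kg arrays, as such runs would give, although single pairs of arrays overlap.

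The poly-A controls rose with dose by more than the genes did. Relative to each array's gene median they were 0.75 higher at 10 mg/kg with a standard error of 0.17, so the shift of the scale could not be the whole cause. Preparation batches that follow the dose groups might give such a rise, and at 0.1 mg/kg, within the arrays that share equal values with vehicle, it was 0.33 with a standard error of 0.16. That interval reaches from near 0 to most of the rise at 10 mg/kg, and since no batch is named in the labels, preparation and dose cannot be told apart at 10 mg/kg. At 1 mg/kg the rise did not follow the dose group: the controls stepped up by 1.22 (SE 0.20) from arrays 1 to 4 to arrays 5 to 10, which argues against a batch of that whole group but leaves a batch boundary inside it open. Arrays 1 to 4, without raised controls, gave 3615 genes against vehicle, or 1833 after quantile normalization. Between the parts 8 genes differed, or 7 after quantile normalization. By the same test of random orders, the first 3 arrays of the vehicle group were higher than the later ones (p = 0.035). The largest step did not pass that test at 0.1 mg/kg (p = 0.493) or at 10 mg/kg (p = 0.602). A change in the messenger RNA content of the liver RNA stays open as a biological explanation and was not tested.

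Macrophage markers were lower at 10 mg/kg on both scales. A smaller share of all cells other than hepatocytes would lower the markers of every such type, but over markers at log2 5 or more with vehicle, those of macrophages changed by -0.58 more than those of endothelial cells (SE 0.13) and by -0.93 more than those of stellate cells and fibroblasts (SE 0.15), after quantile normalization. These standard errors are over arrays and do not cover the spread between markers of a cell type. The compared lists held 9, 6 and 4 such markers, and those of T and natural killer, B, bile duct cells and neutrophils 0, so these types stay uncompared and a loss shared with other immune cells stays open. The shift of the scale ran upward, against their mean change of -0.70 with a standard error of 0.13 on the deposited scale. Fewer macrophages and lower expression per macrophage may each account for this, and no test here separates them. With an estimated correlation the list's adjusted p was 0.0369, and 0.109 after quantile normalization.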

How the results depend on the processing

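Chosen after the data were seen were the settings with hybridisation controls, poly-A controls, quantile normalization together with the filter, 2 arrays left out, single arrays left out and only arrays 1 to 4 of the 1 mg/kg group, and quantile normalization for lists, overlap and dose course, while the others were planned. Leaving out single arrays and keeping only arrays 1 to 4 of the 1 mg/kg group were run for counts of genes, not for named genes. Under the other settings for genes the named genes gave 2792 values. Of these, 2695 kept their direction and side of the threshold, 88 lost the threshold, 4 gained it and 5 changed direction. The 5 came from another probe set of the same gene: Aig1 at 0.1 mg/kg (-0.067), Plin2 at 1 mg/kg (-0.13) and at 10 mg/kg (-0.081), Cyp4a8 at 10 mg/kg (0.03) and Cd5l at 10 mg/kg (0.22), and the cause was not tested. Counts of changed genes that moved by over 1.5 times are given in the order 0.1, 1 and 10 mg/kg against vehicle, then 0.1 to 1 and 1 to 10 mg/kg, where they apply. A required change beyond 1.2-fold gave 4, 914, 3154, 1137 and 264 genes, fewer by construction. Scaling to the hybridisation controls gave 7, 1737, 4024, 2114 and 1151, which also adds the spread of these controls. Fitting only the 2 groups gave 7 at 0.1 mg/kg, and the cause was not tested. With fewer genes tested, the filter on dim genes gave 3177, 3882, 3590 and 1423 from 1 mg/kg on, and 1383 genes in dose order. Quantile normalization, which removes the shift between groups, gave 3106 at 1 mg/kg, 2942 and 2462 for the steps and an overlap of 2556 between 1 and 10 mg/kg. Together with the filter it gave 1588, 3134, 1237 and 1260, and with the poly-A level as a covariate 2805, 5061, 3043 and 2524. With only arrays 1 to 4 of the 1 mg/kg group, fewer arrays, the count there was 3615, and 1833 with quantile normalization too. Shifting to 1 median gave 4071 from 0.1 to 1 mg/kg. Against odd-numbered vehicle arrays for the lower dose the overlap of 1 and 10 mg/kg was 3107, with fewer arrays. Gene lists called fell with an estimated correlation to 3, 10 and 16 at the 3 doses, and at 0.1 mg/kg numbered 2 with fry, which asks another question, and 16 with the filter. Other priors, array weights, other choices among probe sets and leaving out 0.1 mg/kg arrays 8 and 9 kept all 5 counts within 1.5 times, the last with 5398 genes changed between 0.1 and 1 mg/kg. Leaving out each array in turn gave 11 to 15, 5262 to 5844, 8403 to 8818, 5875 to 6614 and 3796 to 4335. Signal over background limits dim genes, whose changes from the floor are compressed or depend on the correction.

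The replicate numbers share no stated link between groups. The correlation of deviations over 60 pairs ran from -0.324 to 0.474, with 24 over 0.1, so that the numbers were not taken to pair the arrays. A hint of pairing remains, since 9 of 40 arrays were closest to an array of their own number where chance gives 4, and 6 of the 10 pairs of 1 and 10 mg/kg were over 0.1. The replicate number as a block gave 14, 5654, 8659, 6560 and 4111 genes and 10, 23 and 35 lists, and changed no count by over 1.5 times.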

Other observations

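The rule that a rise or fall needs both scales was chosen after the data were seen, and so were the counts over other splits of the arrays. Cholesterol synthesis genes rose in part at 10 mg/kg, with 8 of 18 that rose and 0 that fell. Insig1, which holds back sterol synthesis, rose 3.06-fold, from 8.66 ± 0.71 to 10.27 ± 0.34 (log2, mean ± SD, n = 10 each), and Lss, lanosterol synthase, 2.13-fold. The list did not stand apart from other genes on the deposited scale (adjusted p = 0.124), and stood higher after quantile normalization (adjusted p = 0.0278), a call that was lost at adjusted p = 0.486 with an estimated correlation. Glucose and glycerol handling was mixed, with 5 of 18 genes of gluconeogenesis and glycogen that rose and 4 that fell. Gpd2, which oxidises glycerol 3-phosphate, rose 5.90-fold next to the glycerol channels, and Ugp2, which makes the precursor of glycogen, changed by -1.56. The list's median log2 change was 0.10 and its test pointed lower without passing (adjusted p = 0.188). Asns, asparagine synthetase, rose 3.23-fold, and the glutathione transferases Gstm5 and Gsta3 rose 3.44-fold and 2.38-fold, while 13 of the 17 measured transferases did not pass on both scales.

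Immune and clock lists held some genes that changed at 10 mg/kg, but none of these lists passed with an estimated correlation. Of 19 interferon-stimulated genes 5 fell and 0 rose, with Oas1a, a sensor of viral RNA, at -0.86 and the transcription factor Irf7 at -0.79. The list had adjusted p = 0.000105, lost at adjusted p = 0.196 with an estimated correlation. In antigen presentation 4 of 14 fell and 1 rose, with the class II gene RT1-Ba at -1.20, and that call was lost at adjusted p = 0.207 with an estimated correlation. Of 15 circadian clock genes 5 rose and 4 fell, with the repressors Nr1d1 up 2.23-fold, Per3 up 1.94-fold, both from dim levels, and Bhlhe40 at -1.01, and the list did not pass (adjusted p = 0.174).

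The counts of changed genes were set against other splits of the same arrays into groups of the same sizes, with 100 splits each, the real one included. At 0.1 mg/kg 1 split, the real one, gave as many as 13 genes and the highest other gave 2. At 1 mg/kg 1 split gave as many as 5594, with 1101 as the highest other, and at 10 mg/kg 1 split gave as many as 8627, with 4756 as the highest other. For the steps, 1 split each gave as many as 6506 and 4110, with 2478 and 370 as the highest others, and for the dose course 1 split gave as many as 9540, with 128 as the highest other. Chance can be excluded at a share of 0.05 for the count at 0.1 mg/kg. The splits used the deposited scale only, where the shift at 1 and 10 mg/kg can by itself set the real split apart. For the other counts they therefore cannot separate a response to dose from that shift. For gene lists, 3 splits gave as many as 23 at 1 mg/kg, with 25 as the highest other. At 10 mg/kg 1 split gave as many as 35 lists, with 31 as the highest other. This excludes chance for both at a share of 0.05 on the deposited scale, without separating dose from the shift of that scale. At 0.1 mg/kg 6 splits gave as many as 10 lists, with 11 as the highest other, so chance could not be excluded for that count of lists. The median of the other splits was 4, 7 and 11 lists at 0.1, 1 and 10 mg/kg. The list test with the preset correlation thus often called lists for arrays grouped at random.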
